A study of Mus musculus with 12 samples.

How the data were processed

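The series holds RNA sequencing of primary mouse hepatocytes, 12 libraries in all. Per the labels, total RNA was extracted with TRIzol and sequenced on a BGISEQ-500 instrument 48 h after transfection of siRNAs. The cells were kept in Williams' E medium with 10% fetal bovine serum, 2 mM glutamine, 100 nM dexamethasone and 5% insulin, transferrin and selenium supplement. Groups were taken from the sample titles, and the replicate number names the mouse per the series' design text.

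For every library the authors deposited estimated read counts per gene (expected counts, not normalised and partly fractional) and TPM values (transcripts-per-million). Per the submitters' processing notes, Trim Galore 0.6.4 and kallisto 0.4.6 were used with the GRCm38.p6 build. The annotation used for counting, the strand setting and any filter are not given in the sources used here. The files list 55385 Ensembl gene identifiers, in a column whose header names another kind of identifier. Of these, 54487 matched the GENCODE M21 annotation with their version and 55144 without it, and 241 remained without a symbol, with 0.003% of the counts. Counts per library summed to 22453445 to 25008195. Replicates differed by more than counting error, so tests used the spread between libraries.

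Expected counts were rounded and analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr over the 4 groups (at least 0.42 CPM), which left 15090 genes tested and 40295 not tested. Scaling was by TMM, with factors from 0.947 to 1.038. A quasi-likelihood model with 1 mean per group was fitted to all 12 libraries with 8 residual degrees of freedom. All comparisons were two-sided contrasts of this model: each knockdown against siCon, the double knockdown against each single one, siHnf4a against siCebpa, and the interaction (double knockdown minus siHnf4a minus siCebpa plus siCon). P values were adjusted by Benjamini-Hochberg over the tested genes with a threshold of 0.05, and "rose", "fell", "higher" and "lower" refer to genes past it. Values after ± are standard errors for log2 fold changes and SDs for CPM.

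The comparisons, gene lists, alternatives and the rule for naming genes were chosen before the data were examined. Named genes are Hnf4a, Cebpa and Alb in every comparison; per knockdown against siCon and for the interaction, the 6 largest positive and 6 largest negative log2 fold changes past the threshold, with a mean of at least 10 CPM, 1 sign in all 3 mice and an assigned symbol; per described list up to 4 members past the threshold with the largest changes, or the most abundant member where none passed; and any liver transcription factor of the list. Not every gene taken by this rule is printed, and genes said to rise or fall most are the extremes among those it takes. Lists covered liver functions, stress and inflammation, factor-dependent genes and markers of other cell types. Each was tested with camera in limma 3.58.1 (preset correlation 0.01, adjusted over the lists of 1 comparison), with an estimated correlation as the alternative. The list symbols Glycat and Fcn3 were not found, and C5 was read as Hc. Named genes were checked for overlap with genes on the other strand.

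Other alternatives were DESeq2 1.42.0, RLE size factors, no filter on low counts (at least 1 count), a stricter filter (1 CPM in at least 3 libraries), mouse as a block (6 residual degrees of freedom), only the compared groups, limma-trend on log2 TPM with a pseudocount of 1 for genes of at least 1 TPM in 3 libraries, the test fry, and leaving out each library in turn. The mouse numbers were checked on residuals: libraries of 1 mouse correlated with r from 0.16 to 0.68 over 18 pairs, and 12 of 12 correlated best with a library of their own mouse. The test was also run on simulated data with 200 changed genes, where 56 of 100 genes changed by 1 log2 unit and 89 of 100 changed by 2 were recovered and 6 of 151 calls were false. Correlations, slopes and overlaps between comparisons that share siCon were set beside 20 simulations in which all 12 libraries were drawn independently from the siCon means, so that the simulated controls are shared and the mice are not modelled. In 12828 protein-coding genes, the log2 fold change was regressed on the presence of each of 15774 words of 7 bases in the 3' UTR. Fold changes beyond 2 log2 units either way were set to 2. The regression was adjusted for UTR length and base composition, and p values by Bonferroni over the words. Genes were its units, so these p values ignore genes that change together and the spread between mice. A further 233 tested protein-coding genes were not searched. Further steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.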

Results

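Hepatocytes, the parenchymal cells of the liver, were isolated from 3 mice and treated in primary culture for 48 h with small interfering RNAs (siRNAs). These short duplexes direct the degradation of a matching transcript. Total RNA was sequenced in 12 libraries that fall into 4 groups of 3. The groups received a control siRNA (siCon), an siRNA against Hnf4a (siHnf4a), an siRNA against Cebpa (siCebpa) and both together (the double knockdown). Hnf4a encodes a nuclear receptor and Cebpa a basic leucine zipper protein, and both are transcription factors that maintain hepatocyte gene expression. The replicate number names the mouse, so every mouse contributed 1 library to each group. Estimated counts per library summed to 23731068 to 25008195 in siCon, 23885931 to 24806320 in siHnf4a, 23809523 to 23933735 in siCebpa and 22453445 to 24229630 in the double knockdown. Between 14118 and 14516 genes per library reached 10 counts, and 15090 genes entered the test. The 10 most abundant genes took 7.18% to 10.88% of a library's counts and mitochondrially encoded transcripts 2.34% to 4.04%.

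The series title places the question on the stability of albumin transcription, so the siRNA targets and Alb were read first in every library. Hnf4a (ENSMUSG00000017950.16, chromosome 2, 163506808 to 163572910, plus strand, GRCm38) was at 229.6 ± 78 counts-per-million (CPM; SD, n = 3) in siCon, 54.09 ± 6.8 in siHnf4a, 211.1 ± 74 in siCebpa and 35.92 ± 3.67 in the double knockdown. Against siCon it fell by 2.08 ± 0.28 log2 units in siHnf4a and by 2.68 ± 0.29 in the double knockdown (log2 fold change ± SE; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.000953 and 0.000233). Cebpa (ENSMUSG00000034957.10, chromosome 7, 35119293 to 35121928, plus strand) was at 192.8 ± 16.2 CPM in siCon, 214.4 ± 17 in siHnf4a, 30.02 ± 3.81 in siCebpa and 94.2 ± 13.1 in the double knockdown. It fell to 15.6% of siCon in siCebpa (-2.68 ± 0.13, adjusted p = 7.05e-06) and to 48.8% in the double knockdown (-1.03 ± 0.12, adjusted p = 0.000441). Its level in the double knockdown exceeded that in siCebpa by 1.65 ± 0.13 log2 units (adjusted p = 5.11e-05). Both targets were lower than in siCon in each of the 3 mice wherever their siRNA was given.

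Alb (ENSMUSG00000029368.10, chromosome 5, 90460897 to 90476602, plus strand), the gene for serum albumin, was at 7905 ± 1810 CPM in siCon, 8502 ± 2930 in siHnf4a, 8879 ± 4370 in siCebpa and 5453 ± 1870 in the double knockdown. Neither siRNA alone gave a difference larger than the spread between replicates. The log2 fold change was 0.10 ± 0.38 in siHnf4a (95% interval -0.73 to 0.94, adjusted p = 0.893). In siCebpa it was 0.17 ± 0.38 (-0.67 to 1.00, adjusted p = 0.857). With mouse as a block in edgeR these were 0.07 ± 0.16 and 0.10 ± 0.16 (adjusted p = 0.771 and 0.729). Both together gave -0.54 ± 0.38 (-1.37 to 0.30, adjusted p = 0.397). With the block it was -0.56 (-0.92 to -0.21, adjusted p = 0.0238), lower in 3 of 3 mice. It was then -0.66 against siCebpa (-1.02 to -0.30, adjusted p = 0.0127). Against siHnf4a it was -0.64 ± 0.16 with the block (adjusted p = 0.308) and -0.64 ± 0.38 without it, past the threshold in neither fit. Over the 13 alternatives that give a p, the adjusted p against siCon ran from 0.0238 to 0.639 and that against siCebpa from 0.0127 to 0.714.

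**Figure D1:**
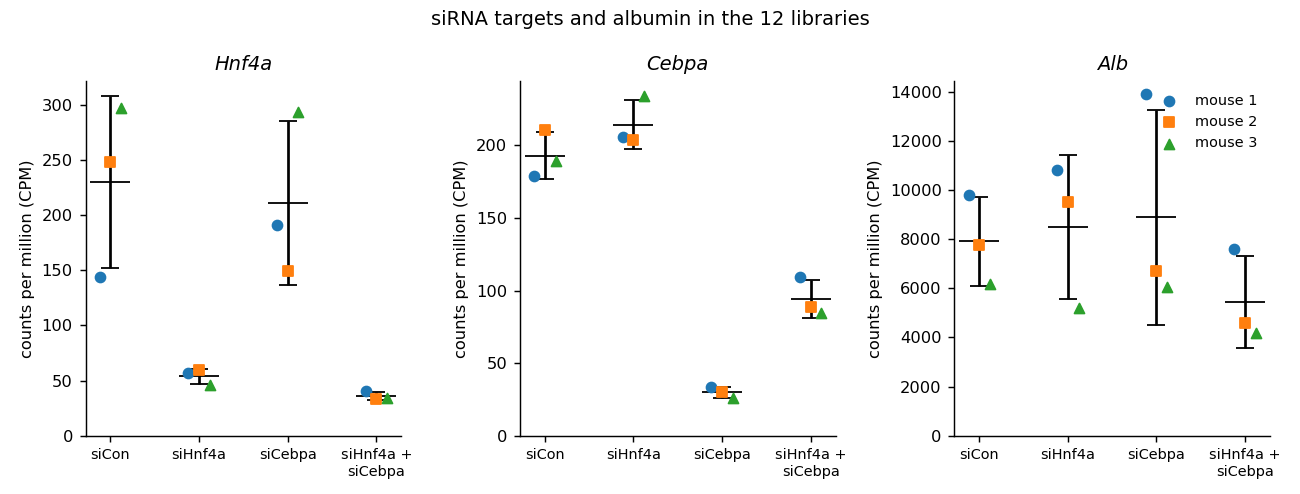
CPM of Hnf4a, Cebpa and Alb (vertical axes, linear from 0) in the 4 groups (horizontal axis), 1 symbol per library and mouse, with bars for the group mean and SD of 3 libraries. Cebpa lay between 26.07 and 33.67 CPM in siCebpa and between 84.5 and 109.1 CPM in the double knockdown, while the Alb values of the groups overlapped.

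Knockdown of Hnf4a alone asked which hepatocyte genes depend on this factor. Relative to siCon, 1093 genes were higher and 1100 lower, of which 249 and 405 changed at least 2-fold. Mup20, a major urinary protein, fell from 281 to 3.6 CPM (-6.29 ± 0.78, adjusted p = 0.000574). It was followed by Cyp2a12, a cytochrome P450 that rehydroxylates secondary bile acids (-4.69 ± 0.52, adjusted p = 0.000326). Next came Smpd3, a neutral sphingomyelinase (-4.24 ± 0.45), Serpinf2, the plasma inhibitor of plasmin (-3.64 ± 0.30), Mettl7b, a thiol methyltransferase (-3.51 ± 0.43), and Acat3, a cytosolic thiolase (-3.49 ± 0.24). The largest rises were those of Adh7, an alcohol dehydrogenase that also oxidises retinol, from 0.955 to 59.3 CPM (5.95 ± 0.46, adjusted p = 4.01e-05), and Il1f9, a cytokine of the interleukin-1 family (4.14 ± 0.39). Derl3, a factor of protein degradation at the endoplasmic reticulum (4.05 ± 0.33), rose as well, with the glutathione S-transferases Gstm3 (3.54 ± 0.29) and Gsta2 (2.68 ± 0.43). Trdc, which encodes the constant region of a T cell receptor chain, also passed (3.01 ± 0.90, adjusted p = 0.0477). However, hepatocytes are not known to rearrange this locus and its call ended in 6 of 13 alternatives, so its identity here is uncertain.

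Among 35 measured liver transcription factors, 5 fell and 4 rose in siHnf4a (the same adjusted over the list alone, 9 lower and 6 higher with mouse as a block). Creb3l3, an endoplasmic reticulum-bound factor of lipid metabolism, fell by 2.30 ± 0.22 log2 units (adjusted p = 0.000106). Smaller falls included those of Foxa3 (-0.68), Tcf7l2 (-0.52) and Nr2f6 (-0.46). Klf15, a glucocorticoid-responsive Krüppel-like factor, rose by 1.00 ± 0.16, and Nr5a2, a nuclear receptor of bile acid synthesis, by 0.65 ± 0.18, beside Stat3 (0.34). Of 28 genes listed beforehand as dependent on HNF4A, 10 were lower and 2 higher (14 lower and 3 higher adjusted over the list alone, 16 lower and 4 higher with mouse as a block). The lower ones included Baat, which conjugates bile acids with taurine or glycine (-3.14 ± 0.53), Apoc2, the activator of lipoprotein lipase (-2.76 ± 0.77, lost in 6 of 13 alternatives), and F12, the Hageman factor of contact activation (-2.56 ± 0.63). Camera gave adjusted p = 2.04e-06 for HNF4A-dependent genes, and 0.647 with an estimated correlation.

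Secreted and lipoprotein genes fell in part. Of 25 genes of apolipoproteins and lipoprotein assembly, 9 were lower and 2 higher (9 lower and 4 higher adjusted over the list alone, 12 lower and 5 higher with mouse as a block). The lower ones included Cideb, which lipidates very-low-density lipoprotein (-2.73 ± 0.27), and Apob, its structural protein (-2.09 ± 0.21). Of 20 complement genes, 4 were lower and 0 higher (7 lower and 0 higher adjusted over the list alone, 13 lower and 0 higher with mouse as a block), and the largest fall was that of Cfb, a protease of the alternative pathway (-1.16 ± 0.24). Of 23 coagulation genes, 4 were lower, such as Proz, the cofactor protein Z (-3.44 ± 0.48), and F5, the cofactor of prothrombin activation (-1.72 ± 0.41), while 3 were higher (5 lower and 3 higher adjusted over the list alone, 8 lower and 6 higher with mouse as a block). Of 30 plasma carriers and protease inhibitors, 5 were lower and 2 higher (6 lower and 4 higher adjusted over the list alone, 15 lower and 5 higher with mouse as a block). Trf, the iron carrier transferrin, fell by 2.06 ± 0.23 and Fetub, a plasma protease inhibitor, rose by 0.84 ± 0.23. Junction genes followed with 5 of 22 lower and 1 higher (9 lower and 1 higher adjusted over the list alone, 10 lower and 1 higher with mouse as a block). The tight junction protein Cldn2 fell (-2.48 ± 0.34) and its relative Cldn1 rose (1.69 ± 0.46). Tested as a whole with camera, adjusted p was 0.000923 for lipoprotein genes, 0.000406 for complement genes, 0.0144 for plasma carriers and 0.000267 for junction genes. An estimated correlation made them 0.647, 0.647, 0.824 and 0.094. Coagulation genes had a camera adjusted p = 0.243, or 0.0358 with mouse as a block and 0.751 with an estimated correlation as well.

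Several lists of stress and detoxification genes held more rises than falls. Of 24 genes of endoplasmic reticulum stress, 11 were higher and 0 lower (1 lower and 13 higher adjusted over the list alone, 1 lower and 15 higher with mouse as a block). They included Creld2 (1.42 ± 0.09), the chaperone partner Dnajb9 (1.38 ± 0.11), Sdf2l1 (1.34 ± 0.17) and the disulfide isomerase Pdia4 (1.12 ± 0.11). Of 24 peroxisome and redox genes, 8 were higher and 2 lower (2 lower and 11 higher adjusted over the list alone). Gclc, the catalytic subunit of glutathione synthesis (2.01 ± 0.17), Srxn1, a sulfiredoxin (1.99 ± 0.14), and Nqo1, a quinone reductase (1.76 ± 0.14), rose, while Pipox, a peroxisomal oxidase of pipecolic acid, fell (-2.98 ± 0.25). Of 27 conjugation enzymes, 9 were higher and 3 lower (the same adjusted over the list alone, 7 lower and 10 higher with mouse as a block). Gstm1 was at 2.35 ± 0.15. Metabolic lists went both ways. In siHnf4a 8 of 34 phase I enzymes rose, such as Fmo1, a flavin monooxygenase (1.42 ± 0.36), and 4 fell (7 lower and 9 higher adjusted over the list alone, 9 lower and 12 higher with mouse as a block). Of 36 genes of amino acid catabolism, 6 rose, such as Tdo2, which opens the ring of tryptophan (1.94 ± 0.34), and 5 fell, such as Ftcd of histidine breakdown (-1.68 ± 0.24; 6 lower and 6 higher adjusted over the list alone, 8 lower and 8 higher with mouse as a block). Of 26 bile acid genes, 5 rose, led by the phospholipid floppase Abcb4 (2.22 ± 0.30), and 4 fell (the same adjusted over the list alone, 5 lower and 12 higher with mouse as a block). None of these 3 lists passed camera (adjusted p = 0.384, 0.437 and 0.289). Of 27 interferon and double-stranded RNA sensing genes, 4 were higher (0 lower and 5 higher adjusted over the list alone, 0 lower and 15 higher with mouse as a block), with a list median of 0.61. Zbp1, a nucleic acid sensor, rose by 1.34 ± 0.40 and the RNA receptor Tlr3 by 0.75 ± 0.18. The camera test gave adjusted p = 7.21e-11 for endoplasmic reticulum stress, 0.00015 for redox genes, 0.0027 for conjugation enzymes and 0.000267 for interferon genes. These became 0.0603, 0.094, 0.647 and 0.824 with an estimated correlation.

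All counts come from edgeR's quasi-likelihood test at an adjusted p under 0.05. Mouse as a block gave 2187 genes higher and 2346 lower, and these included all 2193 called without it. Of 97 called genes that the naming rule took, 56 kept their call whichever of the 6 libraries was left out and none changed sign. The total fell by over 1.5 times without siCon replicate 2 (530 higher, 590 lower), siCon replicate 3 (576, 628) or siHnf4a replicate 2 (587, 550).

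Knockdown of Cebpa alone gave a smaller response, with 444 genes higher and 260 lower, 43 and 56 of them at least 2-fold. Beside Cebpa, the largest falls among genes taken by the naming rule were those of Prg4, the lubricating proteoglycan 4 (-2.74 ± 0.37, adjusted p = 0.00376), and Vim, the intermediate filament protein vimentin, from 801 to 246 CPM (-1.71 ± 0.34, adjusted p = 0.022). Next were Cdc40, a splicing factor (-1.54 ± 0.13), Git1, a scaffold of focal adhesions (-1.36 ± 0.12), and Apon, an apolipoprotein (-1.24 ± 0.21). Derl3 (3.36 ± 0.33, adjusted p = 0.0011), Gstm3 (2.13 ± 0.28), Gsta2 (2.12 ± 0.42), Il1f9 (2.09 ± 0.36), Gsta1 (2.08 ± 0.38) and the carbonyl reductase Cbr3 (1.78 ± 0.20) rose most. Of these, Derl3, Gstm3, Gsta2 and Il1f9 were also among the 6 largest rises in siHnf4a. The word CACCTAC ranked first of 15774 words of 7 bases in 3' untranslated regions (UTRs) for lower expression in siCebpa.

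The lists of endoplasmic reticulum stress and redox genes held more rises than falls here too. In siCebpa 10 of 24 genes of endoplasmic reticulum stress were higher and 0 lower (0 lower and 13 higher adjusted over the list alone). Sdf2l1 (1.39 ± 0.17), Creld2 (0.97 ± 0.09) and Pdia4 (0.95 ± 0.11) were among them. Of 24 peroxisome and redox genes, 7 were higher and 0 lower (0 lower and 11 higher adjusted over the list alone, 0 lower and 11 higher with mouse as a block). Srxn1 was at 1.21 ± 0.14, Gclc at 1.21 ± 0.16 and Slc7a11, the cystine importer, at 1.12 ± 0.27. Conjugation enzymes had 5 of 27 higher (1 lower and 7 higher adjusted over the list alone, 2 lower and 9 higher with mouse as a block). Of 34 phase I enzymes, 3 rose (the same adjusted over the list alone, 5 lower and 5 higher with mouse as a block). These were Cyp2a5, a coumarin hydroxylase with a near-identical neighbour (1.48 ± 0.27), Cyb5a (0.60 ± 0.13) and Ephx1, the microsomal epoxide hydrolase (0.54 ± 0.12). By camera the adjusted p was 1.04e-12 for endoplasmic reticulum stress, 3.85e-09 for redox genes and 0.00334 for conjugation enzymes. With an estimated correlation these were 0.0188, 0.0188 and 0.604.

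Of the 35 liver transcription factors, 4 fell in siCebpa and 1 rose (7 lower and 1 higher adjusted over the list alone, 8 lower and 3 higher with mouse as a block). Creb3l3 (-0.86 ± 0.21), Foxa3 (-0.84 ± 0.16) and Foxa1 (-0.36) were among the lower ones, and Cebpd, a relative of Cebpa, was higher (0.76 ± 0.15). None of the 20 genes listed beforehand as dependent on C/EBPA passed edgeR's test (the same adjusted over the list alone, 2 lower and 1 higher with mouse as a block; median -0.15, camera adjusted p = 0.196). Of 28 HNF4A-dependent genes 2 were lower and 0 higher (3 lower and 1 higher adjusted over the list alone, 5 lower and 1 higher with mouse as a block). Single members passed elsewhere. F11 of the intrinsic clotting pathway fell (-0.89 ± 0.15) and Cpb2, an inhibitor of fibrinolysis, rose (1.23 ± 0.20) among 23 coagulation genes (2 lower and 1 higher adjusted over the list alone, 7 lower and 1 higher with mouse as a block). Hc, complement component C5, fell (-0.81 ± 0.19) among 20 complement genes (the same adjusted over the list alone, 7 lower and 0 higher with mouse as a block). Hadha of mitochondrial fatty acid oxidation fell (-0.67 ± 0.12) among 30 genes of that process (the same adjusted over the list alone, 2 lower and 0 higher with mouse as a block). Of 41 mesenchymal and cytoskeletal genes, 5 were lower and 0 higher (6 lower and 0 higher adjusted over the list alone, 12 lower and 3 higher with mouse as a block). Beside Vim, Fn1, the matrix protein fibronectin (-1.02 ± 0.19), and Flna, which crosslinks actin (-0.55 ± 0.12), fell. Kupffer cell and macrophage markers, 13 genes not of hepatocytes, had a median of -1.17 with 12 of 13 below 0, and 0 passed singly (3 lower with mouse as a block). As a list, camera adjusted p was 0.0107 for liver transcription factors, 0.0454 for HNF4A-dependent genes and 0.00568 for coagulation genes. An estimated correlation made them 0.604, 0.725 and 0.604. Camera gave adjusted p = 0.00208 for complement genes, 0.00334 for mesenchymal genes and 0.00607 for Kupffer cell markers. These became 0.604 each with an estimated correlation.

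The siCebpa counts depended on the fit. Mouse as a block gave 1318 genes higher and 1224 lower, all 704 calls included. A fit of the 6 compared libraries alone called 23 and 22. The deposited length-normalised values (TPM, limma-trend) gave 96 higher and 345 lower, 21.8% higher against 63.1% on counts, with the median of all genes moved to -0.12 log2. Leaving out siCon replicate 2 (59 higher, 58 lower), siCon replicate 3 (61, 53), siCebpa replicate 2 (207, 134) or siCebpa replicate 3 (86, 68) lowered the total by over 1.5 times. Of 43 called genes taken by the rule 14 kept their call whichever library was left out. These were Cebpa, Cbr3, Cdc40, Creld2, Derl3, Gclc, Git1, Gstm1, Gstm3, Nqo1, Pdia4, Prg4, Sdf2l1 and Srxn1.

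Both siRNAs together left 1041 genes higher and 1076 lower than in siCon, 223 and 441 of them at least 2-fold. Mup20 (-7.66 ± 0.85, adjusted p = 0.000282), Cyp2a12 (-5.13 ± 0.54, adjusted p = 0.000209), Cyp3a44, a cytochrome P450 (-4.67 ± 0.93), Smpd3 (-4.65 ± 0.46), Serpinf2 (-4.61 ± 0.32) and Proz (-4.01 ± 0.50) fell most. Adh7 (5.86 ± 0.46, adjusted p = 2.87e-05), Derl3 (4.47 ± 0.34), Il1f9 (4.29 ± 0.39), Gstm3 (3.64 ± 0.29), Trdc (3.33 ± 0.91, uncertain as above) and Itga7, a laminin-binding integrin (2.85 ± 0.49), rose most. Across the 15090 genes the log2 fold changes followed those of siHnf4a with a slope of 0.908 (Pearson r = 0.863), beside r = 0.486 with siCebpa. All 3 comparisons share the siCon libraries, and genes are not independent replicates. In 20 simulations of unchanged groups that also share controls, the slope on siHnf4a was 0.459 to 0.551 and r was 0.451 to 0.546 with siHnf4a and 0.43 to 0.547 with siCebpa. These simulations leave out the mice. The correlation with siCebpa lay within its simulated range, so how much of it comes from shared controls stays open.

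Secretory and lipoprotein lists held more falls than rises. The double knockdown left 10 of 23 coagulation genes lower and 1 higher (the same adjusted over the list alone). F12 was at -3.14 ± 0.65 and F5 at -1.996 ± 0.42. Of 20 complement genes, 9 were lower and 0 higher (11 lower and 0 higher adjusted over the list alone). Falls included those of Hc (-1.72 ± 0.20) and C4bp (-1.34 ± 0.32). Plasma carriers and protease inhibitors had 9 of 30 lower and 0 higher (11 lower and 1 higher adjusted over the list alone, 21 lower and 1 higher with mouse as a block). Igfbp4 (-2.40 ± 0.28), Trf (-2.17 ± 0.23) and Igf1, the circulating growth factor (-1.67 ± 0.40), were among them. Of 25 lipoprotein genes, 10 were lower and 0 higher (the same adjusted over the list alone). Cideb was at -3.29 ± 0.28, Apob at -2.38 ± 0.22 and Mttp, which loads lipid onto Apob, at -1.77 ± 0.18. The list of HNF4A-dependent genes had 13 of 28 lower and 1 higher (17 lower and 1 higher adjusted over the list alone, 20 lower and 1 higher with mouse as a block). The C/EBPA-dependent list had 3 of 20 lower, Trf and Igf1 among them (4 lower and 0 higher adjusted over the list alone, 7 lower and 2 higher with mouse as a block). Tested as a whole with camera, adjusted p was 1.44e-07 for coagulation genes, 3.32e-08 for complement genes and 5.05e-08 for plasma carriers. With an estimated correlation these were 0.177, 0.22 and 0.187. The camera test gave adjusted p = 6.85e-09 for lipoprotein genes, 2.51e-13 for HNF4A-dependent genes and 0.0283 for C/EBPA-dependent genes. An estimated correlation made them 0.159, 0.177 and 0.22.

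Transcription factors in the double knockdown comprised 5 lower and 2 higher of 35 (7 lower and 3 higher adjusted over the list alone, 9 lower and 3 higher with mouse as a block). Creb3l3 (-3.12 ± 0.23, adjusted p = 2.33e-05), the xenobiotic receptor Nr1i2 (-1.16 ± 0.25), Foxa3 (-0.97 ± 0.16) and Nr2f6 (-0.40) were among those that fell. Klf15 (0.95 ± 0.16) and Gata4 (0.34) rose. Of 36 genes of amino acid catabolism, 8 fell and 0 rose (10 lower and 4 higher adjusted over the list alone, 13 lower and 5 higher with mouse as a block). An example is Csad of taurine synthesis (-1.58 ± 0.23). Of 21 genes of gluconeogenesis and glycogen, 4 fell and 1 rose (6 lower and 2 higher adjusted over the list alone, 8 lower and 2 higher with mouse as a block). Of 30 genes of fatty acid oxidation and ketogenesis, 4 fell and 2 rose (the same adjusted over the list alone). Of 24 stress genes of the endoplasmic reticulum, 13 rose and 0 fell (0 lower and 14 higher adjusted over the list alone). Sdf2l1 was at 1.64 ± 0.17 and Creld2 at 1.64 ± 0.09. Of 24 redox genes, 8 rose and 2 fell (2 lower and 10 higher adjusted over the list alone). Of 27 conjugation enzymes, 8 were higher and 6 lower (10 lower and 9 higher adjusted over the list alone, 10 lower and 9 higher with mouse as a block). Sult1a1, a phenol sulfotransferase, fell (-3.21 ± 0.84) and Gsta2 rose (2.81 ± 0.43). The list's median was -0.33 while camera pointed up. Junction genes had 6 of 22 lower and 1 higher (14 lower and 1 higher adjusted over the list alone, 15 lower and 1 higher with mouse as a block). Of 34 phase I enzymes 7 were lower and 4 higher (9 lower and 6 higher adjusted over the list alone, 15 lower and 7 higher with mouse as a block). The 26 bile acid genes had 4 lower and 2 higher (6 lower and 5 higher adjusted over the list alone, 10 lower and 7 higher with mouse as a block). By camera the adjusted p was 0.000451 for amino acid catabolism, 1.08e-16 for endoplasmic reticulum stress, 6.95e-05 for redox genes and 1.09e-05 for junction genes. These became 0.22, 0.0152, 0.07 and 0.0699 with an estimated correlation. Gluconeogenesis genes had a camera adjusted p = 0.0671, or 0.0224 with mouse as a block and 0.485 with an estimated correlation as well. Conjugation enzymes had a camera adjusted p = 0.188, or 0.0241 with mouse as a block and 0.485 with an estimated correlation as well. Phase I enzymes had a camera adjusted p = 0.107, or 0.0356 with mouse as a block and 0.642 with an estimated correlation as well.

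Blocking on mouse gave the double knockdown 2089 genes higher and 2359 lower, all 2117 calls included. Of 91 called genes taken by the rule 64 kept their call whichever library was left out. The total fell by over 1.5 times without siCon replicate 2 (574 higher, 636 lower), siCon replicate 3 (568, 653) or double knockdown replicate 2 (691, 647).

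**Figure D2:**
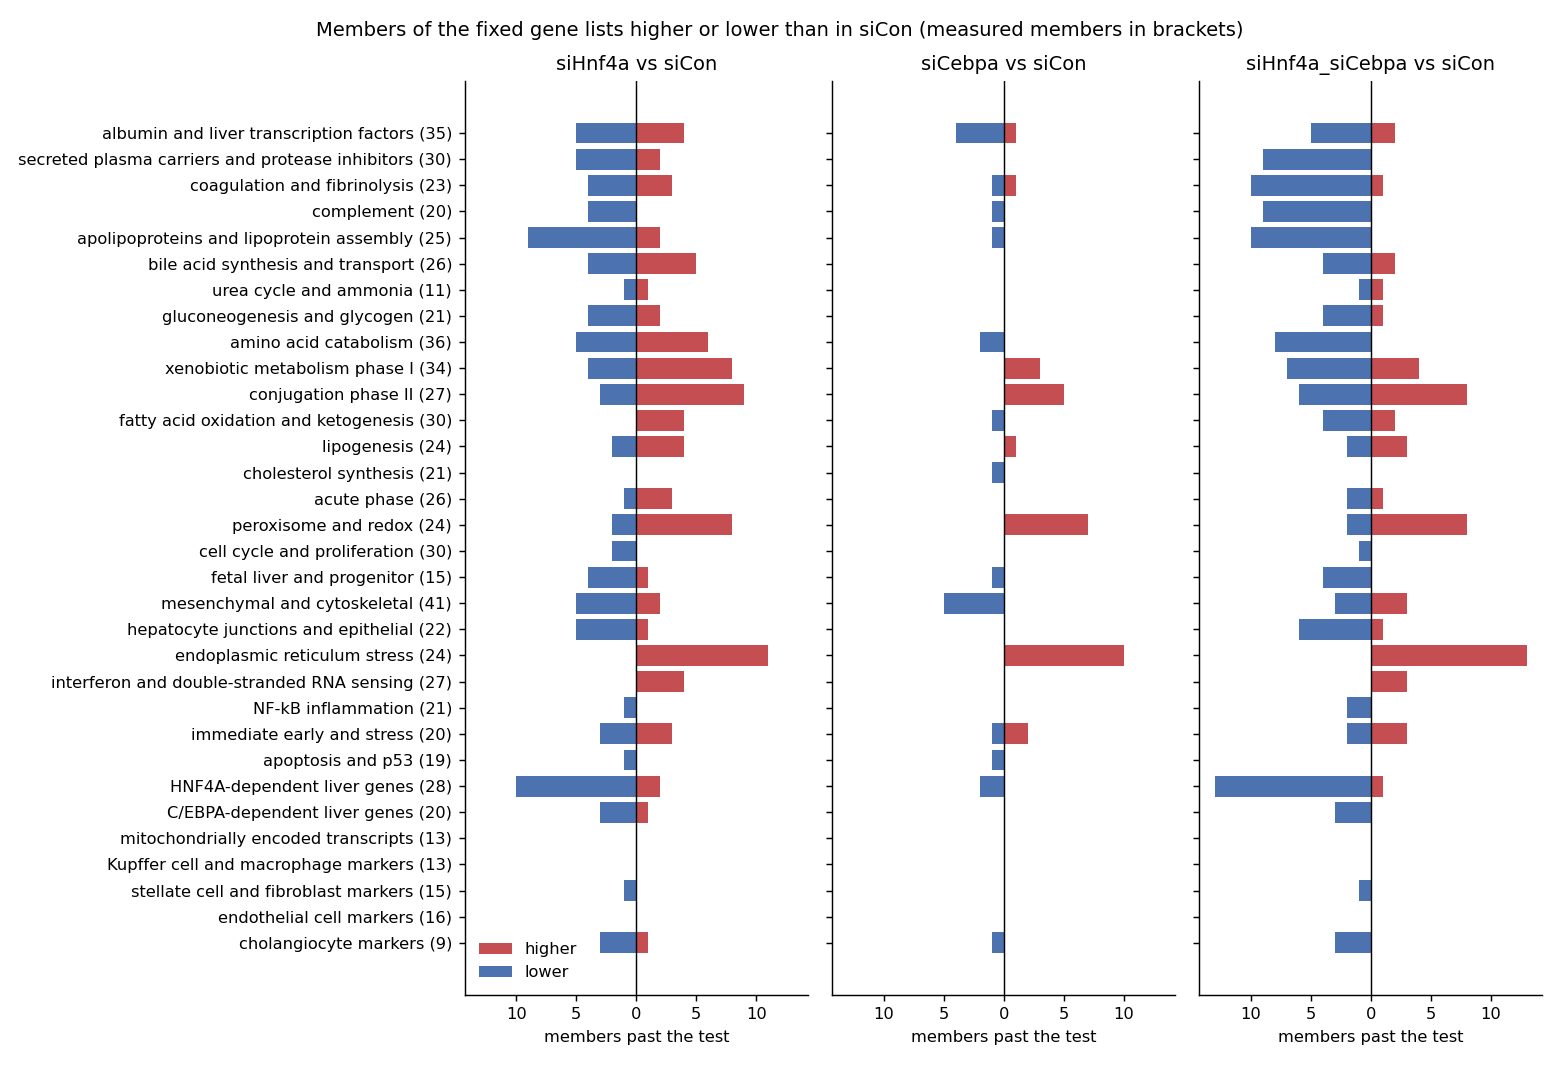
Number of members of each gene list (vertical axis, measured members in brackets) that were higher (right) or lower (left) than in siCon by edgeR at an adjusted p under 0.05 over all tested genes (horizontal axes), for siHnf4a, siCebpa and the double knockdown. The list of endoplasmic reticulum stress has 11, 10 and 13 members higher and 0 lower.

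The remaining lists held few calls in the fit without mouse as a block, and some held many with it. In siHnf4a, siCebpa and the double knockdown, 2, 0 and 1 of 30 cell cycle genes were lower (1, 0 and 1 adjusted over the list alone). Mouse as a block made this 26, 23 and 24. The medians were -1.10, -1.17 and -0.79. Mcm7, a subunit of the replicative helicase, fell in siHnf4a (-0.89 ± 0.10) and in the double knockdown (-0.71 ± 0.10). Camera called the list lower in all 3 comparisons (adjusted p = 0.000267, 7.31e-05 and 0.00306), and in none with an estimated correlation (adjusted p = 0.824, 0.656 and 0.801). The 3 comparisons share the siCon libraries. Fetal liver and progenitor genes had 4, 1 and 4 of 15 lower and 1, 0 and 0 higher (1, 0 and 1 higher and 4, 3 and 5 lower adjusted over the list alone, 4, 0 and 3 higher and 7, 6 and 9 lower with mouse as a block). Sox4, a progenitor transcription factor, fell in siHnf4a (-1.81 ± 0.18) and the double knockdown (-1.64 ± 0.18). Camera gave adjusted p = 0.123, 0.0107 and 0.0177 for that list, and adjusted p = 0.647, 0.545 and 0.22 with an estimated correlation. Interferon genes had 0 of 27 past the test in siCebpa (1 higher and 1 lower with mouse as a block) and 3 higher in the double knockdown (0 lower and 2 higher adjusted over the list alone, 0 lower and 16 higher with mouse as a block). As a list, camera adjusted p was 0.000152 for interferon genes in the double knockdown, and 0.652 with an estimated correlation.

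Of 41 mesenchymal and cytoskeletal genes, 5 were lower and 2 higher in siHnf4a (10 lower and 3 higher adjusted over the list alone, 20 lower and 5 higher with mouse as a block). The double knockdown had 3 of them lower and 3 higher (6 lower and 3 higher adjusted over the list alone, 17 lower and 5 higher with mouse as a block). Ccn2, a matricellular growth factor, was down in both (-2.64 ± 0.46 and -2.24 ± 0.46). Kupffer cell and macrophage markers had 0 of 13 past the test there (4 and 6 lower with mouse as a block), with medians of -0.99 and -1.23. Camera on them gave adjusted p = 0.123 and 0.0283, and adjusted p = 0.824 and 0.624 with an estimated correlation. Cholangiocyte markers had 3, 1 and 3 of 9 lower and 1, 0 and 0 higher in siHnf4a, siCebpa and the double knockdown (1, 0 and 1 higher and 4, 3 and 4 lower adjusted over the list alone, 2, 1 and 1 higher and 6, 4 and 6 lower with mouse as a block). Camera on these markers gave adjusted p = 0.123, 0.0443 and 0.0179, and adjusted p = 0.647, 0.545 and 0.177 with an estimated correlation. Sox9, which hepatocyte progenitors share, was lower in siHnf4a (-1.01 ± 0.24) and the double knockdown (-1.58 ± 0.24). Stellate cell and fibroblast markers had 1, 0 and 1 of 15 lower (0, 0 and 0 higher and 1, 0 and 0 lower adjusted over the list alone, 1, 0 and 0 higher and 3, 0 and 3 lower with mouse as a block). Endothelial markers had 0, 0 and 0 of 16 past edgeR's test (2, 3 and 4 lower and 0, 0 and 2 higher with mouse as a block), with a median of -0.26 in siCebpa. Of the lymphocyte and neutrophil markers 1 was measured, Cd3e (-0.23 ± 0.57 in siHnf4a), and of the red blood cell markers 0 were. Camera gave adjusted p = 0.0101 for mesenchymal genes in siHnf4a, 0.035 for mesenchymal genes in the double knockdown and 0.0297 for endothelial markers in siCebpa. An estimated correlation made them 0.647, 0.627 and 0.604.

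Further lists with calls in siHnf4a, siCebpa and the double knockdown, respectively, were the following. Lipogenesis had 4, 1 and 3 of 24 higher and 2, 0 and 2 lower (5, 1 and 3 higher and 5, 0 and 3 lower adjusted over the list alone, 7, 3 and 5 higher and 5, 1 and 5 lower with mouse as a block). The elongase Elovl6 was up in siHnf4a (1.16 ± 0.17) and the double knockdown (1.13 ± 0.17). Gluconeogenesis and glycogen genes had 2 higher and 4 lower of 21 in siHnf4a (6 lower and 2 higher adjusted over the list alone, 6 lower and 4 higher with mouse as a block). Pfkfb1, a switch enzyme of glycolysis, rose (1.72 ± 0.20). None of the list passed edgeR's test in siCebpa (3 lower with mouse as a block; median -0.37). Fatty acid oxidation genes had 4 of 30 higher in siHnf4a (the same adjusted over the list alone, 4 lower and 9 higher with mouse as a block). Acadm led them (0.99 ± 0.20). Acute phase genes had 3, 0 and 1 of 26 higher and 1, 0 and 2 lower (the same adjusted over the list alone, 4, 1 and 3 higher and 3, 4 and 6 lower with mouse as a block). Mt2, a metallothionein, rose in siHnf4a (1.19 ± 0.23). Immediate early and stress genes had 3, 2 and 3 of 20 higher and 3, 1 and 2 lower (3, 3 and 3 higher and 6, 1 and 3 lower adjusted over the list alone, 3, 3 and 3 higher and 8, 1 and 5 lower with mouse as a block). Gadd45b fell in siHnf4a (-1.40 ± 0.24). In NF-kB inflammation 1, 0 and 2 of 21 were lower (0, 0 and 0 higher and 1, 0 and 1 lower adjusted over the list alone, 1, 0 and 1 higher and 4, 4 and 5 lower with mouse as a block). The macrophage growth factor Csf1 was down in siHnf4a (-1.30 ± 0.19), and in siCebpa the list's median was -0.32. Of the 20 C/EBPA-dependent genes 3 were lower and 1 higher in siHnf4a (the same adjusted over the list alone, 6 lower and 4 higher with mouse as a block). Urea cycle genes had 1, 0 and 1 of 11 higher, Ass1 (0.84 ± 0.16 in siHnf4a), and 1, 0 and 1 lower (1, 0 and 1 higher and 1, 1 and 1 lower adjusted over the list alone, 5, 1 and 1 higher and 1, 2 and 3 lower with mouse as a block). Cholesterol synthesis had 0, 1 and 0 of 21 lower (the same adjusted over the list alone, 1, 0 and 0 higher and 3, 1 and 2 lower with mouse as a block). Apoptosis and p53 genes had 1, 1 and 0 of 19 lower (0, 1 and 0 higher and 0, 1 and 0 lower adjusted over the list alone, 1, 2 and 2 higher and 3, 1 and 1 lower with mouse as a block). Mitochondrially encoded transcripts had 0, 0 and 0 of 13 past edgeR's test with or without mouse as a block. In siCebpa 0 of 26 bile acid genes, 0 of 30 plasma carriers and 0 of 22 junction genes passed edgeR's test (4, 4 and 4 lower and 2, 1 and 0 higher with mouse as a block). Of 25 lipoprotein genes 1 fell (the same adjusted over the list alone, 4 lower and 2 higher with mouse as a block). Amino acid catabolism had 2 of 36 genes lower (3 lower and 0 higher adjusted over the list alone, 7 lower and 2 higher with mouse as a block). Tested as a whole with camera, adjusted p was 0.0253 for gluconeogenesis genes in siCebpa, 0.0176 for NF-kB inflammation in siCebpa and 0.0489 for amino acid catabolism in siCebpa. These became 0.604 each with an estimated correlation.

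The double knockdown (Cebpa at 48.8% of siCon) against siHnf4a tested adding the Cebpa siRNA to the Hnf4a siRNA. edgeR called 1 gene, Cebpa (-1.19 ± 0.12, adjusted p = 0.0188), lower and 0 higher, with 373 genes at an unadjusted p under 0.05. DESeq2 called 3 lower and 1 higher and limma on TPM 1 lower and 0 higher. Lists were then read as a whole. All 23 coagulation genes (median -0.57), all 30 plasma carriers (median -0.41) and 32 of 34 phase I enzymes (median -0.62) had log2 fold changes below 0. The self-contained test fry gave adjusted p = 0.203 for each of these 3 lists, and 0.0367, 0.0466 and 0.0466 with mouse as a block. Adjusted over the list alone, 7 of the coagulation genes, 4 of 36 genes of amino acid catabolism and 2 of 28 HNF4A-dependent genes were lower. Genes of the C/EBPA-dependent list had a median of -0.49 (fry adjusted p = 0.203, or 0.0551 with mouse as a block). Those of endoplasmic reticulum stress had one of 0.15 (fry adjusted p = 0.203, or 0.0254 with mouse as a block). The Cebpa call ended in the fit of the 6 compared libraries alone (adjusted p = 0.218) and without any 1 of siHnf4a replicates 1, 2 and 3 or double knockdown replicates 2 and 3. Its adjusted p reached 0.345 over the 13 alternatives that give a p, with log2 fold changes from -1.32 to -1.12 over all 15. The camera test gave adjusted p = 1.38e-26 for coagulation genes, and 0.0407 with an estimated correlation. For plasma carriers camera adjusted p was 9.26e-15, 0.0583 with an estimated correlation and 0.0422 with mouse as a block as well. For phase I enzymes camera adjusted p was 9.58e-17, 0.0583 with an estimated correlation and 0.0486 with mouse as a block as well. For C/EBPA-dependent genes camera adjusted p was 1.42e-05, 0.0583 with an estimated correlation and 0.0486 with mouse as a block as well. For endoplasmic reticulum stress camera adjusted p was 7.56e-06, 0.0583 with an estimated correlation and 0.0422 with mouse as a block as well.

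The addition of the Hnf4a siRNA to the Cebpa siRNA, the double knockdown against siCebpa, left 983 genes higher and 976 lower. Hnf4a fell by 2.56 ± 0.29 (adjusted p = 0.000398). Of 25 lipoprotein genes, 11 were lower and 1 higher (13 lower and 5 higher adjusted over the list alone, 16 lower and 4 higher with mouse as a block). Of 28 HNF4A-dependent genes, 11 were lower and 0 higher (17 lower and 2 higher adjusted over the list alone, 18 lower and 2 higher with mouse as a block). A block for mouse gave 1964 genes higher and 2157 lower. On the TPM scale 1300 were higher and 371 lower, 77.8% higher against 50.2% on counts. The total fell by over 1.5 times without siCebpa replicate 2 (649 higher, 551 lower), siCebpa replicate 3 (549, 519), double knockdown replicate 2 (619, 434) or replicate 3 (647, 471). By camera the adjusted p was 2.68e-06 for lipoprotein genes and 2.25e-09 for HNF4A-dependent genes. An estimated correlation made them 0.483 each.

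The single knockdowns were set against each other, which tests whether a gene differed between them. In siHnf4a 1133 genes were higher and 1309 lower than in siCebpa. HNF4A-dependent genes differed, with 10 of 28 lower and 2 higher in siHnf4a (13 lower and 6 higher adjusted over the list alone, 16 lower and 6 higher with mouse as a block). Junction genes had 6 of 22 lower and 0 higher (10 lower and 1 higher adjusted over the list alone, 12 lower and 1 higher with mouse as a block). Interferon genes had 6 of 27 higher and 0 lower (0 lower and 7 higher adjusted over the list alone, 0 lower and 16 higher with mouse as a block). Endoplasmic reticulum stress genes differed in 4 higher and 1 lower of 24 (the same adjusted over the list alone, 4 lower and 6 higher with mouse as a block; camera adjusted p = 0.419). A mouse block gave 2246 genes higher and 2466 lower. Tested on TPM, 1596 were higher and 472 lower, 77.2% higher against 46.4% on counts. The total fell by over 1.5 times without siHnf4a replicate 2 (637 higher, 494 lower), siCebpa replicate 2 (787, 706) or siCebpa replicate 3 (663, 695). As a list, camera adjusted p was 0.00364 for HNF4A-dependent genes, 0.0123 for junction genes and 0.000376 for interferon genes. These became 0.91, 0.796 and 0.91 with an estimated correlation.

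The responses to the 2 single knockdowns were compared across the 15090 genes. Called genes coincided in 158 that were higher in both and 64 that were lower in both, while 24 went in opposite directions. Independent lists of these sizes would share 32.2, 19 and 51.2. Simulated unchanged groups that share controls had 0 in common in each of 20 simulations. With no gene changed the test calls hardly any gene, so this 0 was fixed beforehand and cannot gauge the overlap. Blocking on mouse gave overlaps of 547, 555 and 133, beside 191, 190.3 and 382.3 for independent lists. Without a filter on low counts fewer genes coincided in the same direction, as given below. The log2 fold changes correlated with Pearson r = 0.449 and Spearman rho = 0.394, where simulated unchanged groups gave a mean Pearson r of 0.505 (0.455 to 0.537). Their covariance was 0.145 against 0.0798 simulated, a difference of 0.065. The simulations leave out the mice and draw all spread as independent between libraries, so this difference is only a rough guide. The controls could not be split into parts of at least 2 libraries each, so part of the overlap may come from the shared siCon libraries, and genes are not independent replicates.

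**Figure D3:**
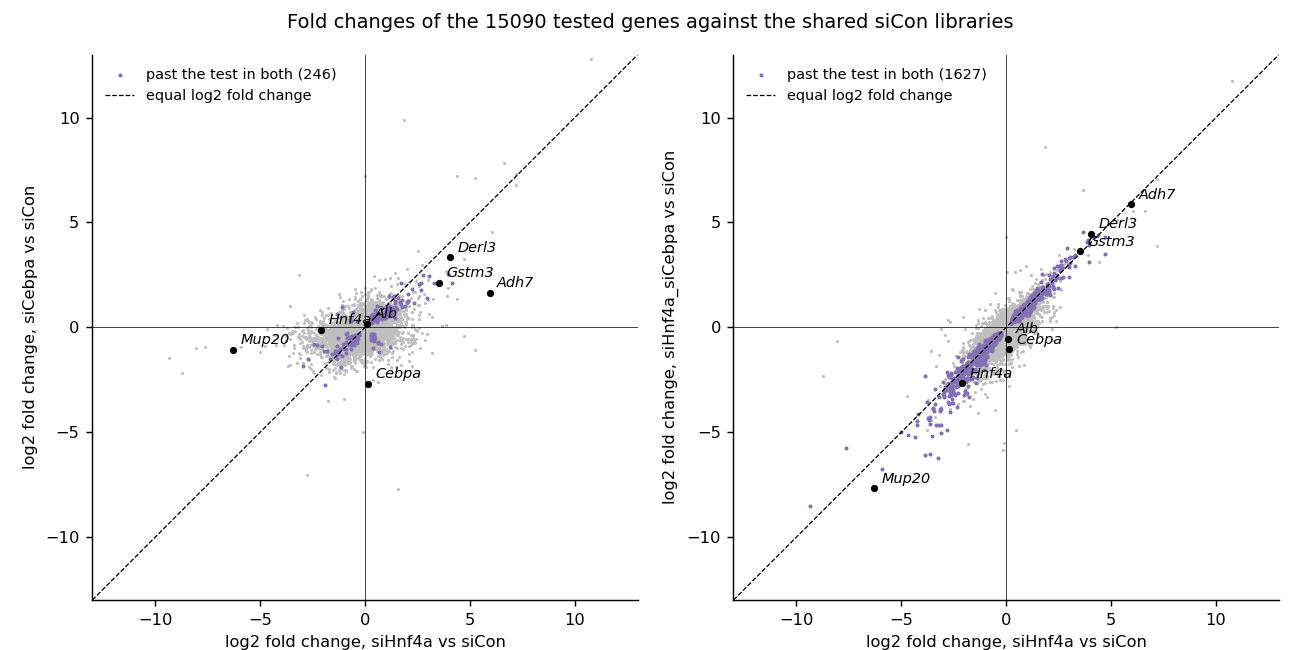
Log2 fold changes against siCon of the 15090 tested genes, with siHnf4a on the horizontal axes and siCebpa (left) or the double knockdown (right) on the vertical axes, 1 point per gene and purple points for genes past edgeR's test in both. Points of the double knockdown lie near the dashed line of equal change (slope 0.908), and Cebpa is labelled at -2.68 in siCebpa and -1.03 in the double knockdown.

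Whether the double knockdown departed from the sum of the single effects was tested as the interaction on the log2 scale. Across genes the double knockdown followed the sum with a slope of 0.582 (r = 0.822). With no group changed, shared controls alone gave slopes of 0.303 to 0.358 and r of 0.515 to 0.621 in 20 simulations. Without a filter on low counts the slope was smaller and close to that range, as given below, but had no simulation. By edgeR 8 genes were higher and 5 lower than additive. The genes higher than additive had fallen in siCebpa, and all but Cebpa lay close to siHnf4a in the double knockdown. They were Cebpa (1.497 ± 0.18, adjusted p = 0.0131), Cdc40 (1.48 ± 0.18, adjusted p = 0.0131) and Git1 (1.38 ± 0.16). Smaller values were those of Capza1, which caps actin filaments (1.06 ± 0.15), Nup205, a nuclear pore protein (1.04 ± 0.14), and Alg2, a mannosyltransferase of N-glycosylation (1.01 ± 0.15). The word CACCTAC occurs in the 3' UTRs of 5 of the 8 genes (Cebpa, Cdc40, Git1, Alg2 and 2310022B05Rik) and not in those of Capza1, Nup205 and Ppp2r1b. Of all genes searched, 6.9% hold it. The word was picked on siCebpa against siCon, whose libraries also enter the interaction, so this count is no separate test. Of the 8 genes, 2310022B05Rik and Ppp2r1b fall outside the naming rule and were chosen after their values were seen. Git1, for example, was at 139 ± 19.2 CPM in siCon, 112 ± 13.5 in siHnf4a, 54.1 ± 4.49 in siCebpa and 114 ± 2.53 in the double knockdown. The genes lower than additive had risen in both single knockdowns. They were Derl3 (-2.93 ± 0.42, adjusted p = 0.0313), Cyp2a4, a steroid hydroxylase (-1.48 ± 0.17, adjusted p = 0.0131), and then Ugt2b35, a glucuronosyltransferase (-1.24 ± 0.16), Cbr1, a carbonyl reductase (-1.03 ± 0.14), and Gsr, glutathione reductase (-0.86 ± 0.12). Cyp2a4 was at 138 ± 6.01 CPM in siCon, 567 ± 12.1 in siHnf4a, 326 ± 52.7 in siCebpa and 479 ± 52.7 in the double knockdown.

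Of the lists that camera with the preset correlation placed lower than additive, the 3 with the smallest p had 0 members past the threshold adjusted over all genes. The interaction had a median of -0.34 in peroxisome and redox genes, of which 5 of 24 were lower and 0 higher adjusted over the list alone (camera adjusted p = 1.16e-08, or 0.0229 with an estimated correlation). In conjugation enzymes the median was -0.72 (camera adjusted p = 5.68e-08, or 0.328 with an estimated correlation), and 7 of 27 were lower and 1 higher adjusted over the list alone. In genes of endoplasmic reticulum stress it was -0.23 (camera adjusted p = 2.41e-06, or 0.17 with an estimated correlation and 0.041 with mouse as a block as well), and 8 of 24 were lower and 0 higher adjusted over the list alone. Mouse as a block left 300 genes higher and 276 lower than additive, the 13 included. DESeq2 called 112 and 122. edgeR called 0 genes, with all 11 named calls lost, without siCon replicate 2 or 3, siHnf4a replicate 1 or 2, or double knockdown replicate 1 or 2, and 4 higher and 2 lower without double knockdown replicate 3. The interaction of Alb was -0.81 ± 0.54 (adjusted p = 0.68, or 0.106 with mouse as a block), below 0 in 3 of 3 mice.

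**Figure D4:**
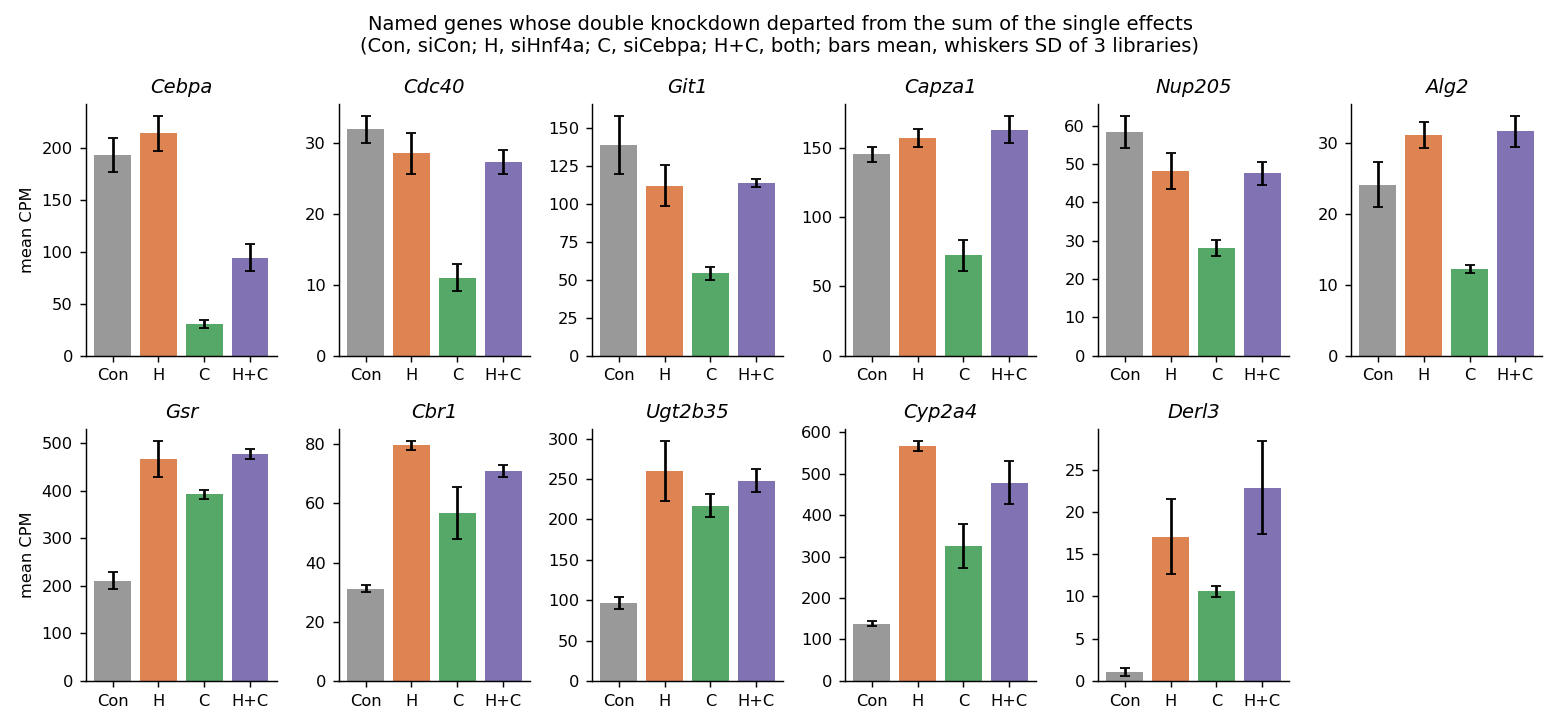
Mean CPM (vertical axes, linear from 0) of the 11 named genes whose interaction passed edgeR's test, in siCon (Con), siHnf4a (H), siCebpa (C) and the double knockdown (H+C), with whiskers for the SD of 3 libraries. Cdc40 and Git1 are low in siCebpa and near siHnf4a in the double knockdown, while Cyp2a4 and Gsr are raised in all 3 knockdown groups.

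Some named genes carry uncertainty from counting. Gsta1, Gsta2, Gstm1, Gstm3, Cyp2a4, Cyp2a5, Cyp2a12, Cyp3a44, Mup20, Ugt2b35 and Sult1a1 belong to families with near-identical members, between which estimated counts can be split wrongly. Acat3, Capza1, Cebpd, Cideb, Csad, Itga7, Mcm7, Mettl7b, Mttp, Nr2f6, Pfkfb1, Prg4, Smpd3, Stat3 and Sult1a1 overlap a gene on the opposite strand with at least 10% of their mean CPM. Whether the counting used strand is not given in the sources used here, so their values are uncertain to that extent.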

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

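The tests in this part were chosen only after the result was seen, except the planned comparisons, the fits without 1 library and the search for words in siCebpa against siCon. The interaction was singled out because it tests whether the effect of the Cebpa siRNA differs between cells with and without the Hnf4a siRNA. In that test 8 genes were higher and 5 lower than additive. The log2 interaction was 1.497 for Cebpa, 1.48 for Cdc40, 1.38 for Git1, 1.06 for Capza1, 1.04 for Nup205 and 1.01 for Alg2. It was -2.93 for Derl3, -1.48 for Cyp2a4, -1.24 for Ugt2b35, -1.03 for Cbr1 and -0.86 for Gsr. The others, 2310022B05Rik (1.51) and Ppp2r1b (0.89), fall outside the naming rule, as said above.

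Other splits of the libraries were counted for each result. For the interaction, limma-trend on log CPM with permuted residuals of the additive model gave at least as many genes as the real 13 in 5 of 100 draws, the real data included, so chance cannot be excluded. The highest other draw called 2553 genes, for which the cause was not tested, and these draws ignored the mice. The same test was run with mouse as a block and residuals permuted within each mouse. It gave 598 genes in the real data and 2 in the highest other draw. Thus 1 of 100 draws, the real one, gave as many, the smallest share that 100 draws can show. This makes chance unlikely for that limma count. The draws were not run for edgeR's blocked count of 576 genes. For the pairwise comparisons 10 splits are too few for a share under 0.05. The real counts were 2193 in siHnf4a, 704 in siCebpa and 2117 in the double knockdown against siCon, 1 in the double knockdown against siHnf4a, 1959 in the double knockdown against siCebpa and 2442 in siHnf4a against siCebpa, and the highest other was 0 in each, among the 4 splits that part all mice as well.

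Genes that fell in siCebpa and were higher than additive in the double knockdown may be partly unintended targets of the Cebpa siRNA. An siRNA seed matches transcripts through 7 bases in 3' UTRs. The word most strongly associated with lower expression in siCebpa was CACCTAC (Bonferroni-adjusted p = 0.000172, effect -0.08 ± 0.01 log2, 888 genes with the word). The p values of words, here and for siHnf4a below, treat genes as independent replicates, which they are not. CACCTAC occurs in the Cebpa 3' UTR, while 13.5% of all words occur somewhere in the Cebpa transcripts. Of the 5 words past Bonferroni adjustment, ACCTACA (adjusted p = 0.00975), which overlaps CACCTAC, occurs in the Cebpa transcripts as well. GGTGGTC (adjusted p = 0.00139), TCCAGAA (adjusted p = 0.0126) and GTGGTCA (adjusted p = 0.0259) do not. GGTGGTC and GTGGTCA overlap each other, so the 5 words are not separate results. TATTTAT, also absent from the Cebpa transcripts, ranked above CACCTAC for the interaction (adjusted p = 7.97e-05 and 0.000182). The interaction holds the siCebpa and siCon libraries on which CACCTAC was picked, so its rank there is no separate support. A seed match is therefore only 1 reading of these words. In the double knockdown against siHnf4a, libraries that did not serve to find the word, the effect of CACCTAC was 0.011 (95% interval -0.009 to 0.031). The association was thus not found again there, although Cebpa itself fell by 1.19 log2 units. A less active Cebpa siRNA in the mixture and a word unrelated to the siRNA would both give this value, so it does not decide. A rise of Cebpa transcripts after loss of Hnf4a is argued against by an upper limit of 0.423 in siHnf4a below the interaction of 1.497. The siRNA sequences are not used here, a further effect of HNF4A loss on these genes stays open, and the 13 calls depend on power. Without any 1 of 6 libraries 0 genes were called, and 6 to 17 without any 1 of the others, while the interaction of Cebpa stayed between 1.381 and 1.585.

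From the lists of redox genes and conjugation enzymes, the 12 members called higher in both single knockdowns were taken. They are named here glutathione and NRF2-type genes. Their medians were 1.73 in siHnf4a, 1.04 in siCebpa and 1.86 in the double knockdown, and the first 2 are raised by this choice. A chance deviation of the shared siCon libraries could raise them in all 3 comparisons. The direct difference between siHnf4a and siCebpa, which needs no siCon library, had a median of 0.63 (quartiles 0.09 to 0.8) with 9 of 12 genes higher in siHnf4a and 3 (Sod1, Gstp1 and Txnrd1) not, which does not decide. Gstm3, Gstm1, Gclc, Srxn1 and Nqo1 kept their siCebpa call whichever of the 6 libraries was left out, so for these no single siCon library carries it. The 20 simulations of unchanged groups called 0 genes higher in both, against 158 here. That 0 was fixed beforehand, as said above, and does not exclude a common shift of the real controls. A response to any siRNA other than the control cannot be told apart from an effect of both factors. The smallest median, 1.04, decides nothing, as the genes were chosen for being higher in both, and the design holds no further siRNA without these targets.

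Genes lower in siHnf4a may also include unintended targets. The word GTGTTTA was the one most strongly associated with lower expression in siHnf4a (Bonferroni-adjusted p = 7.03e-06, effect -0.09 log2), occurs in the coding part of Hnf4a, and was associated again in the double knockdown against siCebpa (adjusted p = 5.09e-07). Of the 4 words past Bonferroni adjustment in siHnf4a, CCCTCTC (adjusted p = 2.96e-05) occurs in Hnf4a transcripts as well, while CCTCTCT (adjusted p = 0.0106) and CCCCCTC (adjusted p = 0.0368) do not. Hnf4a transcripts hold 22.1% of all words, and genes that depend on HNF4A and hold the word would give the same values. The siRNA and the loss of HNF4A therefore cannot be told apart for these genes.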

How the results depend on the processing

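Each result was recomputed under alternatives fixed in advance, and no alternative and no test in this part was chosen after a result was seen. Values past the threshold under neither setting were not counted as turned. Of the 14 gene counts, RLE size factors kept all within 1.5 times and turned 1 named gene. Of the 21 values of Hnf4a, Cebpa and Alb, those past the threshold kept their direction on log2 TPM with a pseudocount of 0.1 or of 1. With either pseudocount Alb went from 0.168 to -0.075 in siCebpa against siCon. In siHnf4a against siCebpa it went from -0.063 to 0.118. The comparison of 6 libraries alone does not exist for the interaction, which needs all 4 groups. The list tests were repeated in this way for the 3 comparisons with siCon and for the double knockdown against siHnf4a, and elsewhere only with an estimated correlation and with mouse as a block. Unless a reason is given, the cause was not tested.

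Mouse as a replicate block removed variation that the animals share between groups, the coefficient of biological variation falling from 0.222 to 0.116. Counts higher and lower became 2187 and 2346 in siHnf4a, 1318 and 1224 in siCebpa, and 2089 and 2359 in the double knockdown. Against siCebpa they were 1964 and 2157 for the double knockdown and 2246 and 2466 for siHnf4a. The interaction gained most in proportion, from 8 and 5 to 300 and 276, and the overlap of calls between the single knockdowns in 1 direction rose from 222 to 1102. In the double knockdown Alb passed against siCon (-0.56) and siCebpa (-0.66), and not siHnf4a (-0.64). Of 22 named genes that passed with the block and not without it, none had the other direction, and 0 calls of named genes ended. Camera with the block called 8 more lists. For siHnf4a adjusted p was 0.0358 for coagulation. For siCebpa adjusted p was 0.0479 for acute phase. For the double knockdown adjusted p was 0.0224 for gluconeogenesis, 0.0241 for conjugation and 0.0356 for phase I. For the double knockdown against siHnf4a adjusted p was 0.0014 for cell cycle, 0.0124 for fetal liver and 0.0272 for junctions. With the block and an estimated correlation as well none of the 8 passed, the values in the same order being 0.751, 0.663, 0.485, 0.485, 0.642, 0.408, 0.107 and 0.387.

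DESeq2 called 786 and 540 genes in siCebpa, 1 and 3 in the double knockdown against siHnf4a, and 112 and 122 for the interaction, and it ended the call of 0 named genes. Without a filter on low counts, which adds genes to the adjustment, siCebpa had 212 genes higher, siHnf4a had 871 lower than siCebpa, the double knockdown 2 lower than siHnf4a, and the interaction 13 and 12. The shared calls fell to 129 and the slope of the double knockdown on the sum of the single effects to 0.376, a move larger than the SD over left-out libraries. The stricter filter gave 13 genes higher for the interaction. A fit of the compared groups alone, with fewer libraries behind the estimate of the spread, gave 23 and 22 genes in siCebpa, 0 lower in the double knockdown against siHnf4a, where Cebpa stayed at -1.19 without passing, 471 and 370 against siCebpa, and 685 and 637 for siHnf4a against siCebpa. It ended 43 calls of named genes. On log2 TPM 96 genes were higher in siCebpa, 371 lower in the double knockdown against siCebpa and 472 lower in siHnf4a against siCebpa, and 33 calls of named genes ended.

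Camera with an estimated correlation between members in place of the preset 0.01 ended 58 list calls and kept the outcome of 70. In siHnf4a adjusted p was 0.0603 for endoplasmic reticulum stress, 0.094 for redox and junctions, 0.647 for complement, lipoproteins, conjugation, mesenchymal and HNF4A-dependent and 0.824 for plasma carriers, cell cycle and interferon. In siCebpa adjusted p was 0.545 for fetal liver and cholangiocyte, 0.604 for liver transcription factors, coagulation, complement, gluconeogenesis, amino acid catabolism, conjugation, mesenchymal, NF-kB, Kupffer cell and endothelial, 0.656 for cell cycle and 0.725 for HNF4A-dependent. In the double knockdown adjusted p was 0.0699 for junctions, 0.07 for redox, 0.159 for lipoproteins and 0.177 for coagulation, HNF4A-dependent and cholangiocyte. Further values were 0.187 for plasma carriers, 0.22 for complement, amino acid catabolism, fetal liver and C/EBPA-dependent, 0.624 for Kupffer cell and 0.627 for mesenchymal. Further values were 0.652 for interferon and 0.801 for cell cycle. In the double knockdown against siHnf4a adjusted p was 0.0583 for plasma carriers, lipoproteins, bile acids, gluconeogenesis, amino acid catabolism, phase I, endoplasmic reticulum stress and C/EBPA-dependent, 0.139 for HNF4A-dependent, 0.197 for complement, conjugation, fatty acid oxidation and cholangiocyte and 0.236 for urea cycle and lipogenesis. Further values were 0.352 for liver transcription factors, 0.41 for acute phase and 0.421 for immediate early.

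The self-contained test fry ended 43 list calls and called 1 more, cholangiocyte markers in siHnf4a (adjusted p = 0.0177). It asks whether a list moves at all, not whether it moves more than other genes, and it takes no preset correlation. Within siHnf4a adjusted p was 0.071 for conjugation and mesenchymal, 0.0997 for complement, 0.185 for plasma carriers and 0.244 for interferon. Further values were 0.261 for cell cycle. Within siCebpa adjusted p was 0.0679 for cholangiocyte, 0.136 for fetal liver, 0.219 for liver transcription factors, conjugation and mesenchymal and 0.238 for Kupffer cell. Further values were 0.255 for coagulation, 0.29 for complement, gluconeogenesis, NF-kB and endothelial, 0.302 for amino acid catabolism and 0.387 for cell cycle. Further values were 0.505 for HNF4A-dependent. Within the double knockdown adjusted p was 0.0955 for mesenchymal, 0.0969 for Kupffer cell, 0.182 for interferon and 0.322 for cell cycle. Within the double knockdown against siHnf4a adjusted p was 0.203 for plasma carriers, coagulation, lipoproteins, bile acids, gluconeogenesis, amino acid catabolism, phase I, endoplasmic reticulum stress and C/EBPA-dependent, 0.323 for cholangiocyte, 0.339 for conjugation, fatty acid oxidation and HNF4A-dependent and 0.36 for lipogenesis. Further values were 0.416 for complement, 0.459 for urea cycle, 0.465 for liver transcription factors and 0.597 for acute phase and immediate early.

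Leaving out 1 library in turn moved 60 of 96 gene counts by over 1.5 times, the group then holding 2 libraries. In siHnf4a 530 to 1057 genes were higher and 550 to 1084 lower, in siCebpa 59 to 491 and 53 to 305, and in the double knockdown 568 to 1010 and 636 to 1033. Against siCebpa the double knockdown had 549 to 1031 higher and 434 to 1095 lower, and siHnf4a 637 to 1366 and 494 to 1514. The double knockdown had 0 to 1 genes lower than siHnf4a, and the interaction 0 to 10 higher and 0 to 7 lower. Cebpa ran from -1.32 to -1.12 in the double knockdown against siHnf4a and from 1.38 to 1.58 for the interaction. Of the named genes 480 calls ended over all libraries left out, and 0 reversed.

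Of the list tests 57 calls ended, 56 were gained and 3 reversed when 1 library was left out. All 3 reversals were in the double knockdown against siHnf4a, where none of the 3 lists was called with all libraries. They were cholesterol synthesis without double knockdown replicate 3 (adjusted p = 0.00347), cell cycle without the same library (adjusted p = 0.0414) and interferon genes without siHnf4a replicate 1 (adjusted p = 0.000159). The lowest and highest adjusted p are given with the group and replicate left out. In siHnf4a they ran from 0.00106 (siHnf4a 1) to 0.149 (siHnf4a 3) for plasma carriers, 0.00761 (siHnf4a 3) to 0.404 (siHnf4a 1) for fatty acid oxidation and 0.0374 (siCebpa 1) to 0.188 (siHnf4a 1) for fetal liver. Other ranges were 2.44e-08 (siHnf4a 1) to 0.0656 (siCon 1) for interferon and 0.00242 (siCon 2) to 0.299 (siHnf4a 2) for Kupffer cell. In siCebpa they ran from 0.000501 (siCebpa 1) to 0.0702 (siCebpa 2) for liver transcription factors, 0.00699 (siCebpa 1) to 0.54 (siCebpa 2) for plasma carriers and 1.12e-05 (siCebpa 1) to 0.104 (siCebpa 2) for coagulation. Other ranges were 7.22e-08 (siCebpa 1) to 0.0589 (siCebpa 3) for complement, 0.00201 (siCebpa 1) to 0.54 (siCebpa 2) for lipoproteins and 0.0151 (siCebpa 1) to 0.877 (siCebpa 3) for bile acids. Then came 0.0151 (siCebpa 1) to 0.956 (siCebpa 3) for urea cycle, 4.42e-05 (siCebpa 1) to 0.176 (siCebpa 3) for gluconeogenesis and 0.0151 (siCebpa 1) to 0.259 (siCebpa 2) for amino acid catabolism. Other ranges were 0.0434 (siCebpa 1) to 0.858 (siCon 2) for phase I, 0.0151 (siCebpa 1) to 0.834 (siCebpa 2) for fatty acid oxidation and 3.38e-06 (siCebpa 1) to 0.956 (siCebpa 3) for acute phase. Then came 0.000288 (siCebpa 3) to 0.0608 (siCebpa 1) for mesenchymal, 0.00974 (siCon 1) to 0.838 (siCebpa 3) for interferon and 0.00017 (siCon 3) to 0.444 (siCon 1) for NF-kB. Other ranges were 4.52e-05 (siCebpa 1) to 0.386 (siCebpa 3) for HNF4A-dependent, 0.0151 (siCebpa 1) to 0.615 (siCebpa 3) for C/EBPA-dependent and 0.037 (siCebpa 2) to 0.81 (siCebpa 1) for stellate cell. Then came 0.000434 (siCebpa 3) to 0.185 (siCebpa 1) for endothelial and 0.0248 (siCon 3) to 0.1 (siCebpa 2) for cholangiocyte. In the double knockdown they ran from 0.0114 (double 1) to 0.193 (double 2) for liver transcription factors, 0.0208 (siCebpa 1) to 0.218 (double 3) for gluconeogenesis and 0.00201 (siCon 3) to 0.229 (siCon 1) for phase I. Other ranges were 2.86e-06 (double 3) to 0.132 (double 1) for cell cycle, 0.00736 (siCon 1) to 0.238 (double 1) for mesenchymal and 6.84e-08 (siCon 2) to 0.0526 (siCon 1) for interferon. Then came 0.0476 (siCon 3) to 0.961 (siCon 1) for NF-kB, 0.0158 (siCon 3) to 0.0582 (siCon 1) for C/EBPA-dependent and 0.000381 (siCon 2) to 0.0932 (siCon 1) for Kupffer cell. Other ranges were 0.00725 (siCon 1) to 0.0545 (double 3) for cholangiocyte. In the double knockdown against siHnf4a they ran from 0.000186 (double 1) to 0.322 (double 2) for liver transcription factors, 0.0124 (siHnf4a 2) to 0.529 (double 2) for lipogenesis and 0.00347 (double 3) to 0.6 (siHnf4a 2) for cholesterol synthesis. Other ranges were 2.76e-08 (double 1) to 0.178 (double 2) for cell cycle, 0.00438 (siHnf4a 1) to 0.664 (double 1) for fetal liver and 0.00378 (double 1) to 0.872 (siHnf4a 1) for mesenchymal. Then came 0.0138 (siHnf4a 3) to 0.701 (siHnf4a 1) for junctions, 0.000159 (siHnf4a 1) to 0.984 (siCon 2) for interferon and 0.00712 (siHnf4a 2) to 0.686 (siHnf4a 1) for immediate early. Other ranges were 6.11e-12 (siHnf4a 1) to 0.378 (double 2) for mitochondrial, 0.000255 (siHnf4a 2) to 0.914 (double 2) for Kupffer cell and 0.0319 (double 2) to 0.742 (siHnf4a 2) for stellate cell. Then came 0.0121 (siHnf4a 1) to 0.999 (double 1) for endothelial and 0.0252 (siHnf4a 3) to 0.42 (siHnf4a 1) for cholangiocyte.

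The depth of 22453445 to 25008195 counts per library limits genes near the filter of 0.42 CPM. In simulated data 56 of 100 genes changed by 1 log2 unit were recovered, so a gene that was not called may still have changed. Alb in the double knockdown, for example, passed only with the block (-0.56).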

Other observations

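The tests in this part were chosen only after the result was seen, apart from the check of the mouse numbers. Libraries of different mice had residuals that correlated with a median r of -0.225, against 0.47 for libraries of 1 mouse. The first 3 principal components of the 12 libraries held 31.2%, 27.8% and 11.2% of the variance.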
